A study of Mus musculus with 4 samples.

How the data were processed

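Total RNA from 3T3-F442A cells, a mouse preadipocyte line that forms fat cells in culture, was hybridised to 4 Affymetrix mouse arrays. Per the labels' protocols, the preadipocytes were infected overnight with a retrovirus carrying a short hairpin RNA, and selected with puromycin at 2 ug/ml for 2 days. Confluent cells were then differentiated with 850 nM insulin for 8 days, with rosiglitazone, an agonist of the nuclear receptor PPAR gamma, added for the first 2 days. Biotin-labelled cRNA was made by the manufacturer's standard procedure, per the labels. The titles place 2 arrays in the group shGFP, the control hairpin, and 2 in the group shTRPV4, the hairpin against the calcium channel gene Trpv4. Nothing in the labels says whether the replicates were separate infections, separate cultures or separate hybridisations. The p-values of single genes therefore measure only the spread between these arrays, which may be technical.

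The values are the submitters' processed table, deposited as 1 linear intensity per probe set and array. The authors' summarisation, background correction and scaling steps are not given in the sources used here, and no detection calls or scanner files were used, so the intensity at which a probe set stands above background is unknown. The 4 columns hold 22626 probe sets, with medians from 129.4 to 144.0 and maxima from 18099 to 19625. Between 1.85% and 2.08% of the values on each array are exactly 1, and 82 probe sets have that value on all 4 arrays. The number of arrays, 2 per group, limits the precision.

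The comparison, its threshold, the rule for scaling, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a later choice is stated. The intensities were taken as log2(intensity + 16). The medians of the 4 arrays on that scale spanned 0.14, more than the 0.1 set as the limit for using the values as deposited, so they were quantile normalized. A fold change is therefore on the log2(intensity + 16) scale, which understates the change of dim probe sets. Where a group reads near or below 16, as for Angptl8, Cox8b, Cxcl10, Oasl2, Cfb, Lep and Etv4, the size depends on the offset. Quantile normalization gives the brightest and dimmest ranks the same value on every array, and 85 probe sets had no spread within either group after it. They include the 82 that were deposited as exactly 1 on all 4 arrays and so had no spread before it. Fabp4 is also among the 85, and its difference of 0 is set by the procedure. The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without an intensity trend) over all 22626 probe sets (Affymetrix control probe sets left out), as arrays labelled shTRPV4 minus arrays labelled shGFP. The fit had 2 residual degrees of freedom and 1.80 prior degrees of freedom, and the threshold was a Benjamini-Hochberg adjusted p under 0.05 over all probe sets. All adjusted p-values of single genes given here are from limma in this way.

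Genes were named from the platform's annotation table. Of the probe sets, 20380 had 1 gene symbol, 691 had several and named no gene, and 1555 were unnamed here. Gene IDs of 20351 of the single-gene probe sets matched the RefSeq table of GRCm38.p6, which changed 0 symbols, and the other 29 kept the symbol of the annotation. A gene with several probe sets was represented by the one with the highest mean over all 4 arrays, which left 12393 genes. Of the 644 genes past the threshold that had another probe set, 504 had all of them in the same direction, and 4 had one past the threshold in the opposite direction. Among the genes of the naming rule past the threshold, at least 1 further probe set did not pass for Bub1, Ccna2, Cpt1a, Csf1r, Cyp51, Des, Ebf2, Fdft1, Flt1, Herpud1, Lyz1, Mcoln1, Mvk, Pank1, Pck1, Sdhc and Srxn1. Probe sets whose IDs end in _x_at or _s_at can read several related transcripts, which holds here for Ces1f, Selenbp1, Lyz1, Dlk1, Srxn1, Mcoln1, Fdft1, Lipa and the representative Ppargc1a probe set. No genome build of the array is given, so no coordinates are reported.

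There were 21 gene lists with 510 entries, of which 56 had no representative probe set and are not analysed here. Each list was tested with camera, limma's competitive set test, with a preset inter-gene correlation of 0.01, and adjusted over the 21 lists. With that preset, the p-values compare a list's genes with the other genes. They do not measure how a list varies between replicate arrays. Of the 21 lists, 13 passed with camera in this way, and 0 did when camera estimated the correlation from the residuals (2 at an unadjusted p under 0.05). Those p-values stand beside each list that passed. The estimate rests on 2 residual degrees of freedom, and so does the test that uses it. For the acute phase list the estimate was −0.0049, below the preset 0.01. Its unadjusted camera p still went from 2.16e-09 to 0.0225. A call lost in this way therefore does not by itself show that correlation removed it. Other lists had estimates above the preset, up to 0.43 for cholesterol synthesis. fry, limma's rotation test of whether a list's genes move on balance in one direction, was a further alternative. The lists cover thermogenic genes, oxidative phosphorylation, fatty acid oxidation, chemokines and cytokines, acute phase and innate immune genes, the interferon response, adipocyte markers, lipogenesis, cholesterol synthesis, preadipocyte and fibroblast markers, extracellular matrix, and the cell cycle. They also cover the unfolded protein and integrated stress response, ERK and immediate early genes, the oxidative stress response, TRP channels, reference genes, and markers of macrophages, muscle, bone and cartilage, and endothelium. A set of 6 further lists, on peroxisomes, branched-chain amino acid breakdown, aldehyde dehydrogenases, the insulin-like growth factor axis, the extracellular proteins of activin, BMP and TGF-beta signalling, and lysosomes, was added later, after the values were seen, and appears only among the closing observations.

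The rule for naming genes took Trpv4, a fixed set of genes whatever their values (Ppargc1a, Ucp1, Cidea, Dio2, Cox8b, Ccl2, Ccl5, Ccl7, Cxcl1, Cxcl10, Il6, Saa3, Fabp4, Adipoq, Pparg and Lep), and the 10 highest and 10 lowest log2 differences among genes past the threshold whose higher group lay above the median level. From each list it took up to 4 members past the threshold with the largest differences, or the 2 with the smallest p where none passed. Genes outside it are marked as chosen after their values were seen.

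The fit was tested on simulated data built from the means and residual spreads of these arrays. Each probe set's residual variance was first moved toward the median variance, so the simulated spreads were more alike than the residual ones. The changed probe sets were drawn from those above the median level. With 200 of 22626 probe sets changed, it called 1 of 50 changed by 0.5 on the log2 scale, 46 of 50 changed by 1, 49 of 50 changed by 2 and 50 of 50 changed by 3. It made 8 calls among 22426 unchanged probe sets. With 3000 changed, it called 737 of 1000 changed by 0.5 and 986 of 1000 changed by 1, and 7.13% of its calls were unchanged probe sets. camera called 20 of 20 simulated lists shifted by 0.5 and 0 of 20 unshifted ones. The simulated noise was independent between probe sets. The count of 0 therefore does not cover lists whose genes vary together, for which the estimated correlation here reached 0.43.

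The alternatives were the values as deposited, median centring, offsets of 1 and 64, leaving out probe sets under the 25th or the 50th percentile of mean level, and a variance prior with an intensity trend, with and without robust estimation. They were also the mean of a gene's probe sets, the replicate number as a block, leaving out each array in turn, a minimum log2 difference of 1, an adjusted p under 0.1, camera with an estimated correlation, and fry. Representing genes by their brightest probe set other than _x_at and _s_at was added after seeing the data.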

Results

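The expression of 22626 probe sets was measured in differentiated 3T3-F442A adipocytes that carried a hairpin against Trpv4, a calcium-permeable cation channel, or a control hairpin against GFP, with 2 arrays per group. The comparison asks which transcripts differ in fat cells in which Trpv4 was targeted. Arrays of the same label were closer to each other than arrays of different labels. The median absolute log2 difference over probe sets was 0.12 between the arrays labelled shGFP and 0.10 between the arrays labelled shTRPV4, against 0.20 to 0.22 across the groups. Pearson's r over probe sets was 0.995 and 0.996 within groups and 0.985 to 0.987 across them. Values below are deposited intensities as mean ± SD (n = 2), with differences on the log2(intensity + 16) scale after quantile normalization.

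The Trpv4 transcript itself was not measurably lower in the arrays labelled shTRPV4. Its single probe set (1417545_at) read 43.7 and 93.8 in the arrays labelled shGFP and 80.1 and 79.5 in the arrays labelled shTRPV4, a log2 difference of 0.32 with a 95% interval from −0.55 to 1.19 (SE 0.31, limma adjusted p = 0.55). The interval leaves room for a lower as well as a higher level. Without replicate 1 of shGFP the difference was −0.09. The knockdown therefore could not be checked on these arrays, and the groups are named by their labels throughout. Of the 10 TRP channel genes measured, 1 rose (also 1 adjusted over the list alone), the lysosomal channel gene Mcoln1 (0.43, SE 0.07, adjusted p = 0.049), a call lost with the values as deposited, when its probe sets were averaged and on its brightest probe set other than _s_at. The list did not pass (median −0.08, camera adjusted p = 0.99).

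Across 12393 genes, 661 were higher and 744 lower in the arrays labelled shTRPV4, and of these 90 higher and 213 lower genes differed by at least 1 on the log2 scale. Several of the lowest encode secreted or sensing proteins of innate immunity. Saa3, an acute phase serum amyloid, fell from 2823 ± 63.6 to 56.7 ± 1.67. On the log2(intensity + 16) scale, used for all fold changes here, the fall was 38.2-fold (log2 difference −5.26, SE 0.06, adjusted p = 0.0050). Lcn2, a siderophore-binding lipocalin, fell 17.1-fold (−4.10, SE 0.16), Lbp, which binds bacterial lipopolysaccharide, 8.80-fold (−3.14, SE 0.07), and the neutrophil chemokine gene Cxcl5 8.45-fold (−3.08, SE 0.10). The rest of the 10 lowest were Cxcl10, Oasl2, Tlr2, Ifit1, Oas1a and Inhba, the activin A subunit, with differences from −3.03 to −2.71. The highest on this scale was Angptl8, a secreted regulator of lipoprotein lipase, which rose from 20.8 ± 11.7 to 360.2 ± 68.8 (log2 difference 3.41, SE 0.28, adjusted p = 0.020). With its control readings around the offset of 16, the size depends on that offset: it was 4.19 (adjusted p = 0.057) with an offset of 1 and 2.35, under Thrsp, with 64. Next was Thrsp, a regulator of lipogenesis, from 36.0 ± 4.78 to 475.4 ± 3.91 (9.81-fold on the log2(intensity + 16) scale, 3.29, SE 0.09). The other 8 of the 10 highest were the carbonic anhydrase Car9 (2.34), the serine protease Prtn3 (2.26), and the carboxylesterase Ces1f (2.25), then Ghrh, which encodes growth hormone-releasing hormone (2.20), and the sulfotransferase Sult1a1 (2.16). Then came Selenbp1 (2.13), the peroxisomal thiolase Acaa1b (2.06) and Retn, which encodes resistin (1.90), with adjusted p from 0.015 to 0.020. The Ces1f and Selenbp1 probe sets are of a kind that can also read related genes. The split depends on scaling: 380 genes were higher and 718 lower with the values as deposited, and 1036 higher and 708 lower with median centring, against 661 and 744 after quantile normalization. With any 1 array left out, or with the replicate number as a block, limma called 0 genes at an adjusted p under 0.05, with 2683 to 4029 genes at an unadjusted p under 0.05. Each of these fits has 1 residual degree of freedom.

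Many chemokine, cytokine, acute phase and interferon-response transcripts were lower in the arrays labelled shTRPV4. Of 32 chemokines and cytokines, 12 fell, 1 rose and 19 did not pass (16 fell and 1 rose adjusted over the list alone). Cxcl1, a neutrophil attractant, went from 6113 ± 170.7 to 966.9 ± 58.4 (−2.65, SE 0.07, adjusted p = 0.015). Il6 went from 274.5 ± 0.226 to 29.7 ± 4.09 (−2.62, SE 0.10). The monocyte attractants Ccl2 and Ccl7 also fell (−2.19, SE 0.08, and −2.43, SE 0.07). The T cell and monocyte chemokine genes Ccl5 and Cxcl10 fell (−1.55, SE 0.11, and −3.03, SE 0.23), the latter to 7.95 ± 5.69, below the offset of 16. The gene that rose, Ccl6, is outside the naming rule and was chosen after its values were seen (1.48, SE 0.19, adjusted p = 0.033). The list was lower as a whole (median −0.38, camera adjusted p = 5.19e-07; adjusted p = 0.27 with an estimated correlation).

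**Figure D1:**
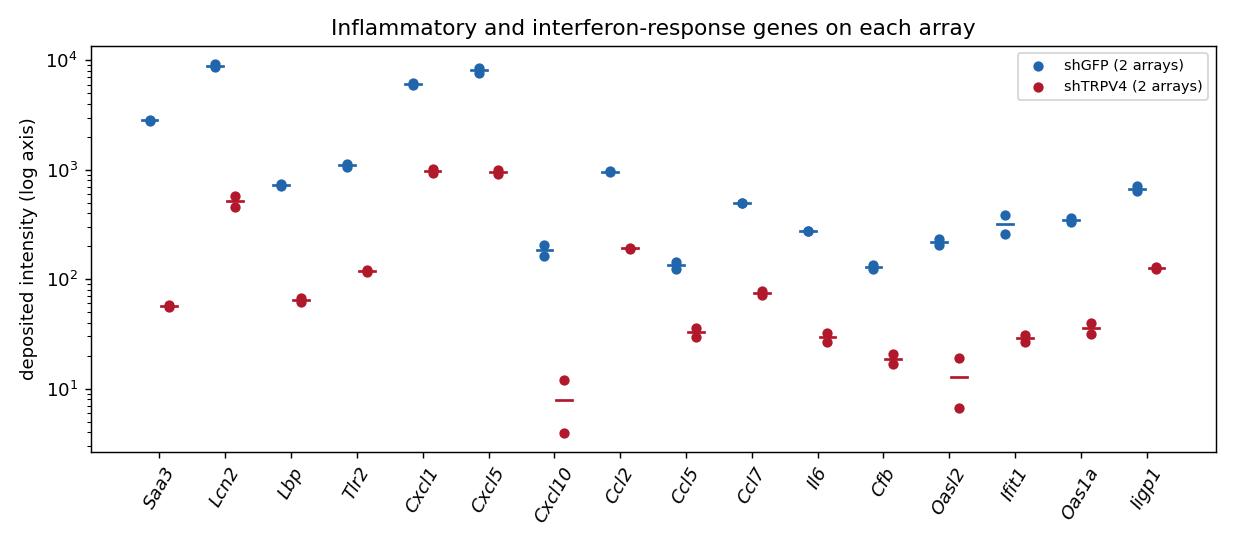
Deposited intensity (log axis) of 16 inflammatory and interferon-response genes on each of the 4 arrays, with a bar at each group's mean of 2 arrays. For every gene shown both shTRPV4 points lie below both shGFP points, by 38.2-fold for Saa3 on the log2(intensity + 16) scale. All 16 are genes of the naming rule that fell past the threshold, so they do not stand for the 3 lists. Of the 79 genes of those lists, 40 fell and 1 rose.

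Among 21 acute phase and innate immune genes, 14 fell and 0 rose (15 fell and 2 rose adjusted over the list alone). Those that fell included Saa3, Lcn2, Tlr2, a receptor for bacterial lipoproteins (from 1101 ± 44.5 to 118.6 ± 2.27, −2.99, SE 0.06), and the complement factor gene Cfb (−2.02, SE 0.09). That list had a median of −0.96 (camera adjusted p = 2.27e-08; adjusted p = 0.27 with an estimated correlation). Of 26 interferon-response genes, 14 fell and 0 rose (19 fell and 0 rose adjusted over the list alone). The oligoadenylate synthetase family members Oasl2 and Oas1a fell (−3.02, SE 0.26, and −2.77, SE 0.13), as did Ifit1, an antiviral RNA-binding protein (−2.84, SE 0.24), and the interferon-inducible GTPase gene Iigp1 (−2.20, SE 0.10). The list had a median of −0.82 (camera adjusted p = 5.57e-10; adjusted p = 0.40 with an estimated correlation). In the same arrays, of 16 macrophage markers 3 fell and 1 rose (also 3 and 1 adjusted over the list alone). Only 1 of the 16 lay above the median level of all probe sets, so a change in the others could have been missed. The lysozyme genes Lyz1 (−1.95) and Lyz2 (−1.89) and, on 1 of its 3 probe sets, the receptor gene Csf1r (−0.85; the others −0.13 and −0.06, adjusted p = 0.78 and 0.83) fell, and Cd68 rose by 1.49 (SE 0.20, adjusted p = 0.035). Of 24 preadipocyte and fibroblast markers, 8 fell in these arrays as well and 16 did not pass (list median −0.36, adjusted p = 0.31 with an estimated correlation). The macrophage list did not pass (camera adjusted p = 0.99), but it did with fry (adjusted p = 0.0384, downward) and, with only Lyz1 left in it, when probe sets under the 50th percentile were left out. The Lyz1 probe set can read both lysozymes. The one without that limit read 9.71 and 12.9, below the offset, and leaves open whether Lyz1 itself fell.

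Many adipocyte and lipid synthesis genes did not pass. Most of those that passed rose, and the ones that fell were adipocyte markers. Of 22 adipocyte markers, 9 rose, 3 fell and 10 did not pass (13 rose and 4 fell adjusted over the list alone). Thrsp and Retn rose as above, Retn from 1405 ± 128.6 to 5249 ± 33.9. Lep, which encodes leptin, fell from 56.1 ± 17.3 to 4.43 ± 0.700 (−1.77, SE 0.20, adjusted p = 0.027), below the offset, which sets the size (−3.32 and −0.79 with offsets of 1 and 64), and Pck1, the phosphoenolpyruvate carboxykinase of glyceroneogenesis, fell from 179.5 ± 44.2 to 25.3 ± 7.06 (−2.18, SE 0.24, adjusted p = 0.026). Pparg, the regulator of adipocyte differentiation, rose by 0.45 (SE 0.07, adjusted p = 0.042), a call lost with the values as deposited. Adipoq, which encodes adiponectin, read 11800 in the arrays labelled shGFP and 13731 in the arrays labelled shTRPV4 (0.16, SE 0.07, 95% interval −0.02 to 0.35, adjusted p = 0.20). Fabp4, the adipocyte fatty acid-binding protein and the brightest of these, read 18160 ± 87.0 and 19384 ± 341.5. Its log2 difference is held at 0 by quantile normalization and was 0.09 with the values as deposited, and none of its 4 probe sets passed. The dimmer ones differed by 0.46 (1424155_at, adjusted p = 0.17), 0.38 (1425809_at, adjusted p = 0.057) and 0.04 (1451263_a_at, adjusted p = 0.77). Chosen after their values were seen, the transcription factor gene Cebpa and the insulin-responsive glucose transporter gene Slc2a4 rose by 0.88 (SE 0.09) and 1.16 (SE 0.19, adjusted p = 0.049), and the lysosomal acid lipase gene Lipa was the third marker to fall (−0.64; lost with the values as deposited and with probe sets averaged). In the same arrays 8 of 24 preadipocyte and fibroblast markers fell (list median −0.36, adjusted p = 0.31 with an estimated correlation). The adipocyte list passed (median 0.34, camera adjusted p = 0.011; adjusted p = 0.50 with an estimated correlation) and, without replicate 2 of shGFP, did not (adjusted p = 0.054, with a range over all alternatives from 0.0013 to 0.50).

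Of 18 lipogenesis genes, 7 rose and 0 fell (10 rose and 1 fell adjusted over the list alone). Besides Thrsp these included the desaturase gene Fads1 (from 1077 ± 60.2 to 1995 ± 100.8, 0.92, SE 0.10, adjusted p = 0.028). The malic enzyme gene Me1 rose too (0.74, SE 0.10, adjusted p = 0.035), as did the acetyl-CoA carboxylase gene Acacb (0.74, SE 0.12, adjusted p = 0.046; lost with the values as deposited). The list median was 0.47 (camera adjusted p = 1.21e-04; adjusted p = 0.40 with an estimated correlation). Of 19 cholesterol synthesis genes, 4 rose and 0 fell (also 4 and 0 adjusted over the list alone). They were the mevalonate pathway kinase genes Pmvk (0.96, SE 0.11, adjusted p = 0.028) and Mvk (0.52), the squalene synthase gene Fdft1 (0.54) and the demethylase gene Cyp51 (0.48). The calls for Mvk and Cyp51 were lost with the values as deposited, and those for Fdft1 and Cyp51 when a gene's probe sets were averaged. The list median was 0.34 (camera adjusted p = 5.55e-04; adjusted p = 0.50 with an estimated correlation), and fry did not call it.

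**Figure D2:**
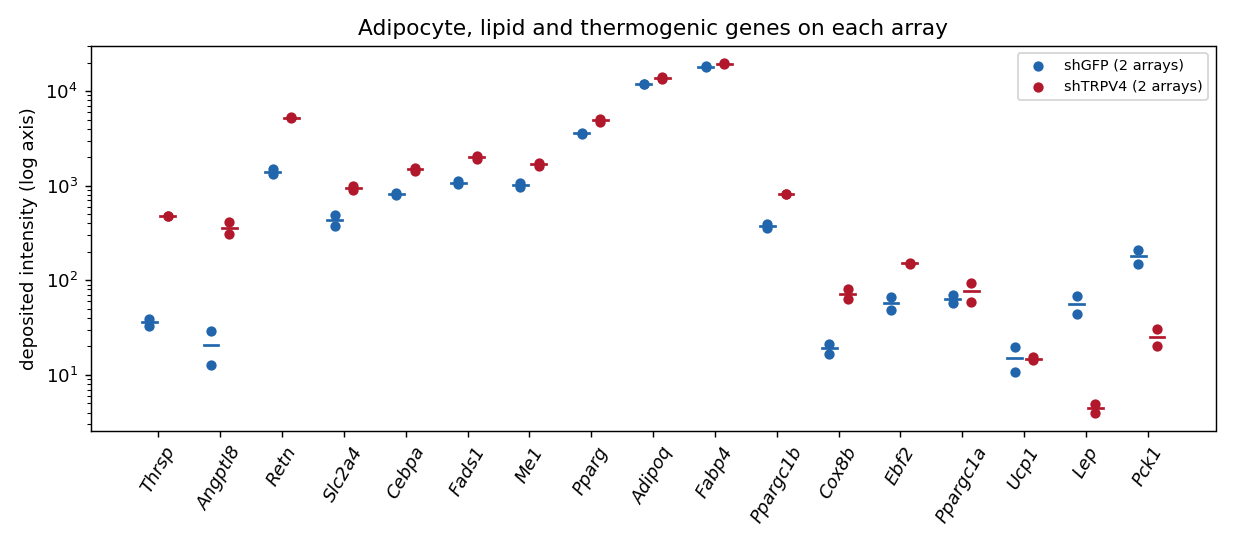
Deposited intensity (log axis) of 17 adipocyte, lipid and thermogenic genes on each of the 4 arrays, with a bar at each group's mean of 2 arrays. Thrsp, Angptl8 and Retn lie higher in the arrays labelled shTRPV4, Lep and Pck1 lower, and the points of Ucp1 and of the representative Ppargc1a probe set overlap between the groups.

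Thermogenic genes were split between a few that rose and others with no measurable difference. Of 15 measured, 4 rose and 0 fell (also 4 and 0 adjusted over the list alone). These were Cox8b, a cytochrome c oxidase subunit typical of brown fat (from 19.1 ± 3.24 to 72.3 ± 11.5, 1.38, SE 0.14, adjusted p = 0.023), and the brown fat transcription factor gene Ebf2 (1.25, SE 0.15, adjusted p = 0.030). The others were the coactivator gene Ppargc1b (from 377.6 ± 23.9 to 826.0 ± 0.120, 1.15, SE 0.07, adjusted p = 0.015) and the pantothenate kinase gene Pank1 (0.72). Ucp1, the uncoupling protein of brown fat, read 15.2 ± 6.16 and 14.8 ± 0.700, below the offset of 16 in both groups (0.01, 95% interval −0.45 to 0.47, adjusted p = 0.98). Cidea, at 23.1 ± 8.13 and 14.3 ± 3.94, around the offset, differed by −0.34 (95% interval −0.88 to 0.19). On its brightest probe set Dio2 differed by −0.16 (−0.67 to 0.34). Its probe sets 1418937_at (0.22) and 1426081_a_at (0.34) had the opposite sign and did not pass either. The probe sets of Ppargc1a, the coactivator of mitochondrial genes, all had positive differences but did not all pass. Its brightest one, 1434100_x_at, did not pass (0.27, SE 0.21, adjusted p = 0.48), nor did 1437751_at (0.24, adjusted p = 0.46). The other 3 of the 5 rose. The brightest probe set other than _x_at, 1434099_at, went from 17.5 ± 2.77 to 60.9 ± 1.91 (1.24, SE 0.09, adjusted p = 0.017). The others rose by 1.23 (1460336_at) and 0.81 (1456395_at). With the 5 averaged, the gene rose by 0.76 (adjusted p = 0.015). Only 2 of the 15 thermogenic genes, Ppargc1b and Pank1, lay above the median level of all probe sets. Leaving out probe sets under the 50th percentile therefore keeps only these 2, both already called as risen. The thermogenic list did not pass (median 0.01, camera adjusted p = 0.15). It passed with probe sets under the 25th or the 50th percentile left out, with probe sets averaged, with fry and without replicate 2 of shTRPV4 (adjusted p = 0.047, with a range over all alternatives from 0.0215 to 0.50).

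Few oxidative phosphorylation genes passed, in arrays in which 8 of 24 preadipocyte and fibroblast markers fell (median −0.36). Of 46 genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone). These were the complex I subunit gene Ndufs1 (0.60, SE 0.06, adjusted p = 0.026) and the succinate dehydrogenase subunit gene Sdhc (0.37, adjusted p = 0.0499; lost with the values as deposited). Of the 46, 39 had a positive difference, with a median of 0.15 (camera adjusted p = 1.89e-04; adjusted p = 0.46 with an estimated correlation). Of 18 genes of mitochondrial fatty acid oxidation, 1 fell and 0 rose (1 and 1 adjusted over the list alone). The gene that fell was Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane (from 875.5 ± 21.3 to 437.6 ± 23.1, −0.93, SE 0.08, adjusted p = 0.020). Its direction was opposite to the list median of 0.20 (camera adjusted p = 0.033; adjusted p = 0.63 with an estimated correlation). The call on that list was lost with either filter on dim probe sets, with fry, without replicate 2 of shGFP (adjusted p = 0.20) and without replicate 1 of shTRPV4 (adjusted p = 0.054), in a range over all alternatives from 0.0045 to 0.63.

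The matrix, stromal, proliferation and immediate early lists had negative medians, though most of their genes did not pass. Of 35 extracellular matrix genes, 12 fell and 2 rose (15 fell and 3 rose adjusted over the list alone). Those with the largest differences were the proteoglycan genes Lum (−2.28, SE 0.16) and Dcn (from 9538 ± 613.2 to 3039 ± 192.4, −1.68, SE 0.07), Thbs1, a matricellular thrombospondin (−2.10, SE 0.10), and the protease inhibitor gene Timp1 (from 7436 ± 1024 to 1952 ± 88.9, −1.94, SE 0.11). The collagen genes Col15a1 (0.97) and Col5a3 (0.50; lost with probe sets averaged), chosen after their values were seen, rose. This list had a median of −0.33 (camera adjusted p = 1.68e-04; adjusted p = 0.39 with an estimated correlation). Of 24 preadipocyte and fibroblast markers, 8 fell and 0 rose (12 fell and 3 rose adjusted over the list alone). The Wnt modulator gene Sfrp2 (−2.35, SE 0.15), Pdgfra, a receptor of adipocyte precursors (from 4333 ± 72.3 to 1793 ± 96.0, −1.25, SE 0.06), the preadipocyte factor gene Dlk1 (−1.24, SE 0.08) and Cd34 (−1.07, SE 0.10) had the largest differences. The list had a median of −0.36 (camera adjusted p = 6.28e-04; adjusted p = 0.31 with an estimated correlation).

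Of 34 cell cycle genes, 9 fell and 1 rose (21 fell and 1 rose adjusted over the list alone). Those that fell included the spindle checkpoint genes Bub1b (−0.99, SE 0.07) and Bub1 (−0.86, SE 0.07), the proliferation marker gene Mki67 (from 334.1 ± 14.7 to 203.6 ± 19.2, −0.62, SE 0.10, adjusted p = 0.049) and Ccna2, a cyclin (−0.57). The gene that rose was Ccne1, another cyclin, chosen after its values were seen (0.54). Over the list the median was −0.36 (camera adjusted p = 3.38e-07; adjusted p = 0.38 with an estimated correlation). Of 22 ERK and immediate early genes, 5 fell and 0 rose (9 fell and 2 rose adjusted over the list alone). They included Dusp6, a phosphatase of ERK (−1.02, SE 0.14, adjusted p = 0.035), Egr1 (−0.99, SE 0.07, adjusted p = 0.018), Etv4 (−0.76, from 17.1 ± 4.50) and Phlda1 (−0.73). The fifth was Myc, chosen after its values were seen (−0.57; lost with the values as deposited). These genes had a median of −0.36 (camera adjusted p = 5.55e-04; adjusted p = 0.31 with an estimated correlation).

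**Figure D3:**
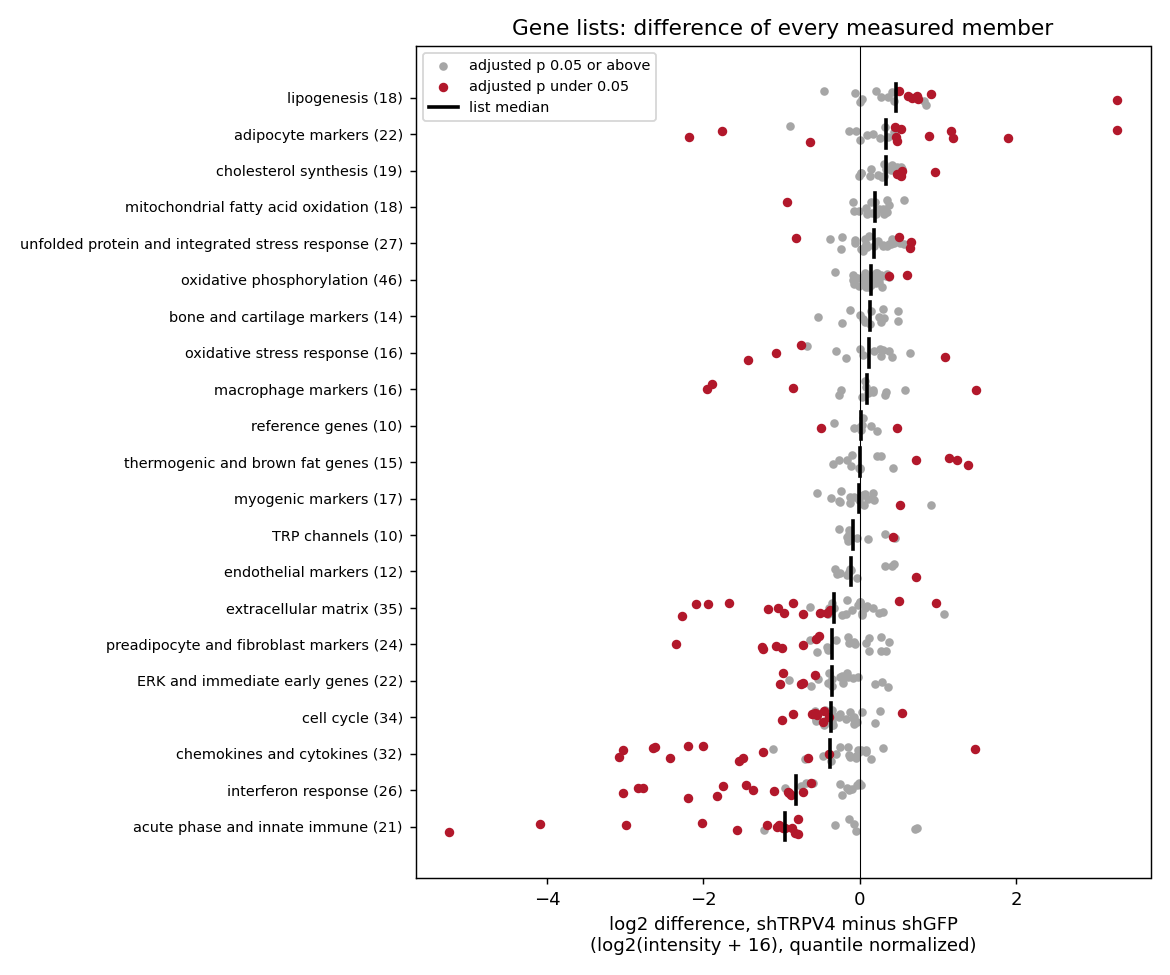
Log2 difference, shTRPV4 minus shGFP, of each measured member of the 21 gene lists fixed beforehand (number measured in parentheses), on the log2(intensity + 16) scale after quantile normalization, 2 arrays per group. Red points have an adjusted p under 0.05, grey points do not, and black bars are list medians, which run from −0.96 for acute phase and innate immune genes to 0.47 for lipogenesis.

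Stress genes moved in both directions. Of 27 genes of the unfolded protein and integrated stress response, 3 rose and 1 fell (9 and 2 adjusted over the list alone). The transcription factor gene Ddit3 (from 1616 ± 178.7 to 2511 ± 63.3, 0.66, SE 0.09, adjusted p = 0.035), the glutathione-degrading enzyme gene Chac1 (0.65) and Herpud1 (0.50) rose, and Atf3 fell by 0.81. The calls for Herpud1 and Atf3 were lost with the values as deposited. The list passed (median 0.18, camera adjusted p = 0.015; adjusted p = 0.40 with an estimated correlation) and did not without replicate 1 of shTRPV4 (adjusted p = 0.054, with a range over all alternatives from 0.0026 to 0.40). Of 16 oxidative stress genes, 3 fell and 1 rose (3 and 3 adjusted over the list alone). The mitochondrial superoxide dismutase gene Sod2 fell from 5697 ± 238.2 to 2111 ± 83.1 (−1.42, SE 0.06, adjusted p = 0.015). Gstm2 (−1.08) and Srxn1 (−0.75) fell too, the latter a call lost on its brightest probe set other than _s_at. The heme oxygenase gene Hmox1 rose from 2880 ± 116.1 to 6194 ± 402.1 (1.09, SE 0.08, adjusted p = 0.018). That list did not pass with camera (adjusted p = 0.99) and did with fry (adjusted p = 0.0119, downward).

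Few markers of other lineages passed, 2 of 43. Most of them were dim. Only 1 of 17 muscle, 1 of 14 bone and cartilage and 1 of 12 endothelial markers lay above the median level of all probe sets. A change in the others could have been missed. Among 17 muscle markers 1 rose, Des (0.52, adjusted p = 0.036; lost with the values as deposited and with probe sets averaged), and among 12 endothelial markers 1 rose, Flt1 (0.72, adjusted p = 0.043), both also 1 adjusted over the list alone. None of 14 bone and cartilage markers passed by limma (0, also 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05). The smallest p-values were those of Alpl (0.31, adjusted p = 0.076) and Chad (0.49, adjusted p = 0.13). The 3 lists had camera adjusted p-values of 0.985, 0.994 and 0.38. Of 10 reference genes, Hprt rose by 0.48 (adjusted p = 0.038) and B2m, a component of class I histocompatibility molecules, fell by 0.49 (adjusted p = 0.033; lost with median centring). The other 8 did not pass (1 rose and 2 fell adjusted over the list alone, median 0.02, camera adjusted p = 0.99). Median, mean and camera direction differed in sign for the oxidative stress, TRP channel, macrophage, muscle, endothelial and reference lists, none of which passed with camera as reported.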

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

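The number of genes past the threshold moved with the settings. It was 1405 (661 higher, 744 lower) in the fit of the report. It was 387 (116 and 271) with an offset of 1 and 2577 (1356 and 1221) with an offset of 64. It was 2487 (1298 and 1189) and 3084 (1714 and 1370) with probe sets under the 25th or the 50th percentile left out. It was 2644 (1408 and 1236) with an intensity trend in the variance prior and 3097 (1659 and 1438) when that prior was also robust. It was 303 (90 and 213) with a minimum log2 difference of 1 and 2872 (1505 and 1367) at an adjusted p under 0.1. The values as deposited gave 380 higher genes and median centring 1036. Scaling moved the median of all probe sets from −0.01 to 0.08. Of the 1405 called genes, 1041 were also called in the same direction with the values as deposited, 379 with an offset of 1 and 1368 with the trend.

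The replicate block gave 0 genes (0 higher, 0 lower; smallest limma adjusted p 0.075, 4029 genes at an unadjusted p under 0.05). Leaving out any 1 array gave 0 to 0 (smallest adjusted p 0.13 to 0.20, 2683 to 3417 at an unadjusted p under 0.05). Each of these fits has 1 residual degree of freedom where the fit of the report has 2, and where 1 array remained in a group it was assumed to vary like the other group. The replicate numbers share only a number: deviations of same-numbered arrays correlated at 0.12 over probe sets, and 2 pairs cannot show a pairing. With the block, the count of lists past the threshold was 13 of 21.

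Of the 21 lists, 13 passed with camera as reported, 0 with an estimated correlation (smallest adjusted p 0.27, 2 lists at an unadjusted p under 0.05), 14 with fry and 11 to 14 under the other settings. Of the 77 named genes past the threshold, 76 kept their direction in each of the 15 settings in which they were measured (51 were in all 15, as the 2 dim filters left out 1 and 26); the exception was Lyz1, at 0.18 on its brightest probe set other than _x_at and _s_at. With the values as deposited 68 of the 77 stayed past the threshold, and with an offset of 1, 43. The cause of these differences was not tested.

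Values near 0 changed sign. The Trpv4 difference ranged from −0.0926 to 0.727 when 1 array was left out. So did Ppargc1a (−0.0014 to 0.54), Dio2 (−0.39 to 0.062; 0.13 with probe sets averaged) and Ucp1 (−0.20 to 0.21; −0.0032 as deposited). List medians that crossed 0 were the thermogenic list (−0.000845 as deposited), TRP channels (0.0060 with median centring, 0.37 and 0.13 under the 2 dim filters), muscle markers (0.052 with median centring, 0.055 with an offset of 1, 0.050 and 0.52 under the filters, and −0.17 to 0.095 without 1 array). They were also endothelial markers (0.33 under the first filter, −0.16 to 0.096 without 1 array), reference genes (−0.00931 with probe sets averaged, −0.0125 to 0.0628 without 1 array), and macrophage markers (−1.95 under the second filter, which leaves only Lyz1). Among the added lists they were the insulin-like growth factor axis (0.022 as deposited, 0.12 with median centring, −0.018 to 0.043 without 1 array) and the activin, BMP and TGF-beta list (−0.69 under the second filter, where it passed, −0.048 to 0.038 without 1 array). None of these lists passed with camera as reported; the thermogenic, macrophage, insulin-like growth factor and activin lists did with fry.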

Other observations

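The tests of explanations in this part were chosen after the results were seen, and so were the 6 further gene lists and the genes named from them, except Inhba and Mcoln1, which the naming rule had taken. As these 6 lists were drawn up with the values known, their p-values are descriptive and no test of the lists. The comparison of Trpv4 and the lists weighed in the last 3 paragraphs were fixed beforehand. The rises in this paragraph came in arrays in which 8 of 24 preadipocyte and fibroblast markers fell (list median −0.36). Of 26 peroxisomal genes, 8 rose and 0 fell (14 and 0 adjusted over the list alone), among them Ephx2, a soluble epoxide hydrolase (1.84, SE 0.11), and Pex11a, a peroxisome proliferation factor (from 1038 ± 6.72 to 2151 ± 32.9, 1.07, SE 0.06). The list median was 0.38 (camera adjusted p over these 6 lists = 7.18e-07; adjusted p = 0.16 with an estimated correlation). Of 20 genes of branched-chain amino acid breakdown, 5 rose and 2 fell (15 and 3 adjusted over the list alone), including Bckdha and Dbt of the branched-chain ketoacid dehydrogenase (0.93, SE 0.07, and 0.77, SE 0.09). Mccc1, Pcca and Bcat2 also rose, and Bcat1 and Auh fell. The calls for Pcca, Bcat2 and Auh were lost with the values as deposited, that for Auh also with median centring and with probe sets averaged, and that for Bcat2 with an intensity trend in the variance prior. The median was 0.40 (camera adjusted p = 7.75e-04; adjusted p = 0.55 with an estimated correlation). Of 16 aldehyde dehydrogenases, 4 rose and 0 fell (5 and 0 adjusted over the list alone), led by the retinaldehyde dehydrogenase gene Aldh1a1 (1.86, SE 0.06) and followed by Aldh1a7, Aldh9a1 and Aldh2. Their list had a median of 0.25 (camera adjusted p = 0.026; adjusted p = 0.52 with an estimated correlation). That call was lost without replicate 2 of shTRPV4 (adjusted p = 0.11, with a range over all alternatives from 0.0066 to 0.52) and with probe sets under the 50th percentile left out.

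Secreted growth regulators moved in both directions. In the insulin-like growth factor axis, 2 of 17 genes rose and 3 fell (3 and 4 adjusted over the list alone). Igf1 rose from 862.2 ± 87.5 to 1816 ± 4.78 (1.10, SE 0.12, adjusted p = 0.026), and the binding protein gene Igfbp3 fell from 906.8 ± 88.9 to 137.1 ± 7.47 (−2.54, SE 0.08, adjusted p = 0.015). Irs1 rose too, and Igf2 (lost with probe sets averaged) and Igfbp6 fell. Of 22 genes for extracellular proteins of activin, BMP and TGF-beta signalling, 4 fell and 1 rose (6 and 1 adjusted over the list alone), with Inhba at −2.71 and its antagonist gene Fst at −2.01 (SE 0.08) falling. The metalloprotease gene Bmp1 and Ltbp2, for a latent TGF-beta binding protein, fell as well, and Ltbp1 rose. Of 33 lysosomal genes, 4 rose and 2 fell (also 4 and 2 adjusted over the list alone). Manba, Neu1, Npc1 and Mcoln1 rose, and Lipa and Lamp1 fell. The calls for Npc1, Mcoln1, Lipa and Lamp1 were lost with the values as deposited, and that for Lamp1 also with median centring. These 3 lists had camera adjusted p-values of 0.75, 0.22 and 0.19 and did not pass as reported, but all 3 passed with fry, the first 2 downward and the lysosomal list upward (adjusted p = 0.0044, 0.0066 and 0.0256). The activin, BMP and TGF-beta list had a median of 0.08 and a mean of −0.25. The lysosomal list also passed with median centring, and the activin list with probe sets under the 50th percentile left out.

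The lower inflammatory and interferon transcripts form a broad pattern, with 40 of the 79 genes of the 3 lists falling and 1 rising. Fewer macrophages in the cultures labelled shTRPV4 stay open by these markers, although a preadipocyte line is not known to hold macrophages. Of 16 macrophage markers 3 fell past the threshold (Lyz2, Lyz1 on a probe set that can read Lyz2, and Csf1r on 1 of 3 probe sets). Cd68 rose. Only 1 of the 16 lay above the median level of all probe sets, so the list cannot decide. Fewer undifferentiated cells stay open as well: the preadipocyte and fibroblast markers had a median of −0.36, and although 11 of the inflammatory genes fell further than the lowest of those markers, expression of the markers in adipocytes could dilute their fall. An interferon or inflammatory state set by the hairpin or the culture rather than by the targeted gene cannot be told apart from an effect of the targeted gene either, because the labels name 1 hairpin per group and the interferon list's median of −0.82 would be the same under both. An effect of lowering Trpv4 also stays open; further hairpins against it, with the transcript measured by quantitative PCR, would test it.

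The adipocyte markers moved apart, with 9 rising and 3 falling. A larger share of differentiated cells in the cultures labelled shTRPV4 would raise them together, whereas 3 fell past the threshold. Pck1 fell on 1 of its 2 probe sets and Lep to readings below the offset. The call for Lipa was lost with the values as deposited and with probe sets averaged. The fall of these 3 was known before the comparison was chosen, so it is no test of that explanation. What moved the adipocyte markers apart stays open. Measuring these genes in fat cells sorted from both cultures would show whether the cause lies within the differentiated cells.

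Trpv4 was not lower in the arrays labelled shTRPV4. An exchange of 1 array of each group is argued against, because 4 of 4 arrays were closest to the other array of their own label. A probe set that reads mostly background stays open, since no detection calls were used and the 2 arrays labelled shGFP differed by 0.83 on the log2 scale, more than the groups did. An exchange of both arrays of each group cannot be told apart from correct labels by this probe set, whose difference of 0.32 did not pass in either direction.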
